A study of Mus musculus with 18 samples.

How the data were processed

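Total RNA was taken from 18 single mouse blastocysts of a BDF1 by C57BL/6 cross at embryonic day 5, and libraries were made with the Ovation Solo RNA-Seq kit, which amplifies cDNA from small inputs. Per the labels, every embryo has an origin, a class and a number. IVF embryos came from zygotes fertilised in vitro and cultured in KSOM medium to the blastocyst stage. VIVO embryos were fertilised in the mother, flushed from the reproductive tract at E2.5 and cultured in KSOM from there. The classes are males, wild-type (WT) females and females with a deleted Xist (KO females). Xist is the long non-coding RNA that coats and silences 1 X chromosome in female cells.

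The submitters' processing notes name the mouse genome build mm10 (GRCm38), bcl2fastq 2.17, Trimmomatic 0.32, TopHat2 2.1.1 and Bowtie2 2.2.3. The tool that produced the counts, the gene annotation release and the use of strand information are not given in the sources used here. The deposited table has 36172 gene entries and 2 columns per embryo, and all 36 columns were matched to an embryo. Per the file headers, 1 column holds a raw read count, but between 60.7% and 76.2% of its values above 0 are not whole numbers at a tolerance of 0.0001, so as deposited the value is an estimated count, which can share reads between genes. The other column is headed RPKM (reads per kilobase of transcript, scaled to the total reads), but its deposited values are log2 RPKM with everything under 1 RPKM set to 0. Over the 13267 genes with a deposited value above 0, the deposited log2 value minus the log2 of the depth-scaled count differed between embryos by at most 4.37e-06. RPKM on a linear scale was therefore recomputed from the estimated counts for all genes, and all RPKM values below are linear. Symbols found on more than 1 entry (75) were kept as separate entries. Gene positions are on GRCm38 from the GENCODE vM21 annotation.

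Total estimated counts ran from 2620758 to 7473533 per embryo. Reads were amplified by PCR and no molecular identifiers were used here to remove copies, so floors and counting limits given here cover counting error only. Where every embryo of a group had a count of 0, the fold is a lower bound computed against 3 counts per library in that group.

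Gene tests used R 4.3.3 and edgeR 4.0.16. Estimated counts were rounded, scaled with TMM (trimmed mean of M values) and fitted with edgeR's quasi-likelihood model with robust dispersion, with 1 mean for each of the 6 groups and all 18 embryos. Genes with a mean of at least 1 RPKM over all embryos were tested, 10425 in all, of which 406 are X-linked with Xist and Tsix left out and 10012 are autosomal. Adjusted p values throughout are from edgeR's quasi-likelihood test, two-sided, with the Benjamini-Hochberg correction over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are log2 with the default prior count of edgeR's fit, and a prior count of 2 was used only for log2 values of single embryos. SE is the standard error of the log2 fold change. It was computed as the size of the fold change over the square root of the quasi-likelihood F statistic. The common biological coefficient of variation was 0.416, with 12.0 prior degrees of freedom. The plan made before the data were examined had foreseen RPKM alone and limma on log2(RPKM + 1). Since the table also held counts, the edgeR test was chosen after the values were seen, and the planned limma test (limma 3.58.1) was run as an alternative.

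The 12 comparisons, the gene lists, the rule for named genes and the measures of the X chromosome were chosen before the data were examined. The comparisons are KO against WT females within each origin and the difference of the 2, IVF against VIVO within each class and their mean, WT females against males and KO females against males within each origin, and the difference in the effect of origin between WT females and males. Comparisons share embryos, so they are not independent of each other. The X shift is the median log2 fold change of X-linked genes minus that of autosomal genes, tested with camera from limma at a preset inter-gene correlation of 0.01 and adjusted over the 12 comparisons. The X-to-autosome level is the same difference of medians within each embryo on log2(RPKM + 1), tested with exact two-sided permutation tests that permute labels within strata.

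Of 30 gene lists, 22 had at least 5 tested members and were tested with camera, adjusted over the lists of a comparison. They are the X-inactivation centre, genes that escape X inactivation, the Xlr, Magea and Fthl17 families, canonical and non-canonical imprinted genes, epiblast and pluripotency, primitive endoderm, trophectoderm, 2-cell stage, p53 targets, integrated stress response, unfolded protein and heat shock response, oxidative stress response, glycolysis, cholesterol synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, MAPK feedback, DNA methylation, Polycomb, cell cycle and apoptosis. The Rhox cluster, Y-linked genes, oocyte genes and markers of cumulus cells, oviduct and uterine epithelium, sperm and blood had fewer than 5 tested members and are given as genes. The mitochondrially encoded genes are absent from the table, so that list was not tested. Camera sets a list against all other tested genes, most of them autosomal. A list whose members are all X-linked can thus pass on an X shift alone. Because a preset correlation can call too many lists, each list was also tested with the correlation estimated from the data, and with fry. The directional p of fry asks whether the genes of a set move on balance one way, the mixed p whether they change in either direction, and neither compares the set with other genes or sets.

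Genes are named by rule. For each comparison these are up to 10 called genes per direction with the largest fold change whose groups do not overlap, the 5 of smallest p in a direction with fewer than 5 calls, up to 4 members of smallest p from each list described, and Xist, Tsix, Rlim and the Y-linked genes always. Predicted genes are passed over. For the mean of the origin comparisons and for differences of effects the groups may overlap.

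Recovery was tested on simulated negative binomial counts with known fold changes put in, drawn from each gene's mean over all embryos, each embryo's library size and the fitted dispersions. Of genes raised or lowered 4-fold, 66.0% were called in the KO against WT comparison of IVF embryos, 52.0% in that of VIVO embryos, 76.0% between IVF and VIVO males and 90.0% in the mean of the origin comparisons. For 2-fold changes the shares were 22.0%, 14.0%, 20.0% and 64.0%. An X shift of 0.58 put into the data was returned as 0.54 to 0.60.

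The alternatives were limma on log2(RPKM + 1), on log2(RPKM + 0.1), with quantile normalization, with array weights and on the deposited log2 RPKM; DESeq2 1.42.0; edgeR with DESeq2's size factors; no filter; only the groups compared; the embryo number as a block; an estimated inter-gene correlation; and each embryo left out in turn. Quantile normalization and array weights were run within limma on log2(RPKM + 1), so they change the test as well. IVF KO females 3 and 4 were also left out together, a choice made after the data were seen because these 2 embryos held the fewest detected genes. This leaves 1 IVF KO female, so the spread there comes from the other groups. Permutation tests and figures used Python with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Allele-specific expression was not analysed here, since the table holds no allele counts.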

Results

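RNA was sequenced from 18 single blastocysts in 6 groups: IVF KO females (n = 3), IVF WT females (n = 3), IVF males (n = 3), VIVO KO females (n = 3), VIVO WT females (n = 2) and VIVO males (n = 4). The total estimated count per embryo was 3534430 to 4166171 in IVF KO females, 5219719 to 5714492 in IVF WT females and 6244166 to 7473533 in IVF males. It was 4940286 to 6780025 in VIVO KO females, 5355482 to 5694392 in VIVO WT females and 2620758 to 6536890 in VIVO males. The ribosomal RNA precursor Rn45s took 5.13% to 12.4% of the counts. Correlations between embryos of the same group ran from 0.831 to 0.949. The labels do not say whether the embryos of a group came from separate litters. The p values of single genes and of permutation tests thus measure the spread between these embryos. Camera compares genes with other genes, so its p values rest on the spread across genes and do not measure the spread between embryos alone. In each value below, ± is the SD over the embryos of a group.

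Xist (X, 103460373 to 103483233, minus strand, GRCm38), the deleted gene, separated the groups as labelled. The 3 IVF WT females had 289, 376 and 394 RPKM and the 2 VIVO WT females 863 and 806 RPKM. The 3 IVF KO females had 1.47, 10.5 and 19.1 RPKM, from 110 to 1210 counts, and the 3 VIVO KO females had 0.632, 4.31 and 0.780 RPKM, from 56 to 524 counts. The background in the 3 IVF males was 0.260 to 0.403 RPKM and in the 4 VIVO males 0.286 to 0.469 RPKM. Xist thus stood above the male level in every KO female. The labels do not say which part of Xist is deleted, so exons left in place are not excluded as the source of these counts. Xist overlaps its antisense gene Tsix (X, 103431517 to 103484957, plus strand), and because the use of strand is not given, reads in the overlap cannot be assigned with certainty. On log2(RPKM + 1), Xist was lower in KO than in WT females by -5.40 within IVF and -8.39 within VIVO, with a mean of -6.90 (exact permutation test within origin, two-sided, p = 0.005, the smallest that 200 permutations can give). The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had no count in any female, and Uty had 2 counts in 1 IVF KO female.

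**Figure D1:**
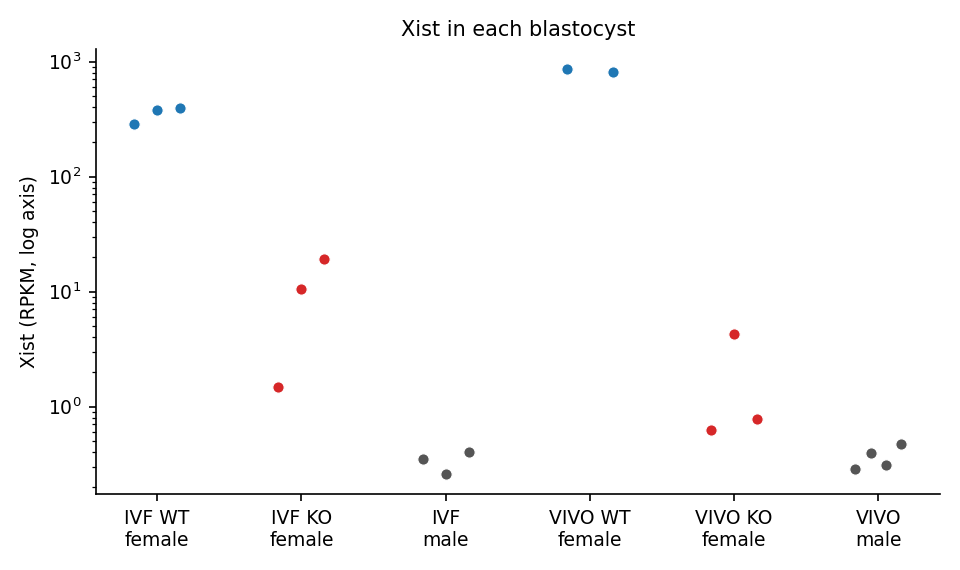
Xist in each of the 18 embryos by group, in RPKM on a log axis. WT females lie between 289 and 863 RPKM, KO females between 0.632 and 19.1 RPKM and males between 0.260 and 0.469 RPKM.

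The first question was how the transcriptome of a female blastocyst changes without Xist. In IVF embryos, X-linked genes as a group were higher in KO females (n = 3) than in WT females (n = 3): the X shift was 0.85 on the log2 scale, or 1.80-fold, and 87.2% of the 406 X-linked genes had a fold change above 0 (camera adjusted p = 1.79e-34, and adjusted p = 1.13e-06 with an estimated correlation). Among single genes, Xlr4a (X, 73074345 to 73082507), a member of an X-linked family expressed in lymphoid and germ cells, rose from 10.2 ± 3.65 to 66.6 ± 20.4 RPKM (log2 fold change 2.69, SE 0.46, adjusted p = 0.00663). Nxt2 (X, 142227937 to 142239692), an mRNA export cofactor, rose from 1.78 ± 1.14 to 17.4 ± 7.93 RPKM (log2 fold change 3.25, SE 0.56, adjusted p = 0.00663). The homeobox gene Rhox5 (X, 37754608 to 37808878), which is subject to imprinted X expression, rose from 4.61 ± 2.9 to 80.9 ± 32 RPKM (log2 fold change 4.08, SE 0.80, adjusted p = 0.0138). The autosomal transcription factor Klf5 (14, 99298691 to 99313409), which acts in the inner cell mass and trophectoderm, fell from 487 ± 33 to 247 ± 7.4 RPKM (log2 fold change -1.02, SE 0.17, adjusted p = 0.00446).

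In all, 107 genes were called in IVF embryos, 67 higher and 40 lower in KO females. The 67 comprised 48 X-linked and 19 autosomal genes. The 40 comprised Xist (log2 fold change -5.16, SE 0.86, adjusted p = 0.0178) and 39 autosomal genes, so no other X-linked gene was called lower. At an unadjusted p under 0.05 there were 1472 genes. With each embryo's trend on transcript GC content as an offset, 75 of 9821 genes were called, 36 of them X-linked and higher. Without it 104 of the same genes were called, 47 of them X-linked and higher, and 66 calls were shared. The GC trends of the IVF KO females went in opposite directions. Their rank correlations with GC content were -0.254, -0.296 and 0.351 in KO females 3, 4 and 8. The 2 groups did not overlap for 106 of the 107, and for 15.3% of all tested genes, where chance gives 10%. AV320801, an X-linked gene, was at least 49.3-fold higher in KO females, in whom it reached 7.27 ± 4.87 RPKM against no count in WT females. Gulo (14, 65986787 to 66009210), the enzyme of the last step of vitamin C synthesis, was at least 9.37-fold higher. The small nucleolar RNA Snord83b fell from 427 ± 234 to 32.7 ± 9.30 RPKM (log2 fold change -3.77, SE 0.60, adjusted p = 0.00424), and Snord49b and Snord104 were lower as well, with log2 fold changes of -3.94 (SE 0.92, adjusted p = 0.0383) and -3.17 (SE 0.63, adjusted p = 0.0138).

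The list of the Xlr, Magea and Fthl17 families, X-linked genes of near-identical copies whose reads cannot be assigned to single members with certainty, had 4 of 14 members called higher over all genes and 12 adjusted over the list alone. Its median log2 fold change was 1.70, above the 0.86 of all X-linked genes, and the list test held with an estimated correlation (adjusted p = 3.61e-16, and adjusted p = 0.0204 with an estimated correlation). All 14 members are X-linked and the test sets them against all tested genes, so the X shift alone can make the list pass. No test set the list against other X-linked genes. Of the 4 tested genes of the Rhox cluster, homeobox genes of the placenta and germ line, only Rhox5 was called over all genes, and 4 were higher adjusted over the list alone, with a median of 3.88. The integrated stress response, the genes that ATF4 controls under amino acid shortage, had a median of -0.80 with 0 of 21 members called over all genes and 8 lower adjusted over the list alone (adjusted p = 1.26e-06). This call was lost in the stricter test (adjusted p = 0.433 with an estimated correlation). The lists of cholesterol synthesis (median 0.36, adjusted p = 0.000945, 6 of 21 members higher adjusted over the list alone) and p53 targets (median 0.62, adjusted p = 0.013, 1 of 17 higher adjusted over the list alone) had no member called over all genes and were lost too (adjusted p = 0.433 with an estimated correlation for both). Cytosolic ribosomal proteins had a median of -0.17 with 1 of 30 called lower (adjusted p = 0.0158), lost as well (adjusted p = 0.989 with an estimated correlation). That member was Rps27, with a log2 fold change of -1.0 (SE 0.23, adjusted p = 0.0352). The X-inactivation centre list, which holds Xist itself, had a median of 0.74 but a mean of -0.30 and did not pass camera (adjusted p = 0.863, and adjusted p = 0.989 with an estimated correlation) or the directional test of fry, but passed its mixed test (adjusted p = 0.036). Its members Rlim, which encodes an activator of Xist, and Tsix were not called, with log2 fold changes of 0.48 (SE 0.22, adjusted p = 0.317) and 0.74 (SE 0.42, adjusted p = 0.45). Insulin-like growth factor 2 (Igf2), an imprinted gene, had a log2 fold change of -1.18 (SE 0.27, adjusted p = 0.0352).

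The number of calls in IVF embryos rests on single embryos. It was 641 without IVF KO female 8, 35 without KO female 3, 42 without KO female 4, and 28, 29 and 27 without WT females 2, 4 and 8. Among the genes given here, Rhox5 was no longer called without IVF WT female 2 (adjusted p = 0.0889), 4 (0.0503) or 8 (0.0627). Xist was lost without KO female 4 (0.068) or WT female 4 (0.0503) or 8 (0.0557), and AV320801 without any of the WT females (0.0503 to 0.0576). Their fold changes kept direction and size. The call of Klf5 held each time. Igf2 and Rps27 were each lost in 5 of the 6 settings that leave out 1 embryo, with adjusted p up to 0.16.

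In VIVO embryos the X shift between KO (n = 3) and WT females (n = 2) was 0.81, or 1.76-fold, with 82.5% of X-linked genes above 0 (camera adjusted p = 1.81e-30, and adjusted p = 1.13e-06 with an estimated correlation). Hprt (X, 52988078 to 53021660), the purine salvage enzyme used as a classic marker of X dosage, rose from 190 ± 2.4 to 776 ± 64 RPKM (log2 fold change 2.1, SE 0.26, adjusted p = 0.000202). Pgk1, the X-linked glycolytic enzyme, rose from 29.1 ± 3.29 to 94.3 ± 15 RPKM (log2 fold change 1.77, SE 0.36, adjusted p = 0.0278), and Rlim from 61.5 ± 5 to 142 ± 12 RPKM (log2 fold change 1.28, SE 0.26, adjusted p = 0.0278). The primitive endoderm transcription factor Sox7 (14, 63943706 to 63950732) fell from 6.77 ± 2.5 to 0.0972 ± 0.17 RPKM (log2 fold change -5.91, SE 1.05, adjusted p = 0.0213). Lefty2 (1, 180893119 to 180899102), a secreted inhibitor of Nodal signalling, was at least 23.1-fold lower, with no count in KO females against 4.76 ± 0.77 RPKM in WT females. VIVO males, given below, were about as low as KO females for Sox7 and Lefty2. For these genes an effect of the deletion thus cannot be told apart from a trait of the 2 WT females.

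Of 31 genes called in VIVO embryos, 24 were higher and 7 lower. X-linked genes made up 23 of the 24, and Arrdc4 was the autosomal one (log2 fold change 2.48, SE 0.54, adjusted p = 0.0424). The 7 lower were Xist (log2 fold change -8.67, SE 1.03, adjusted p = 0.00471) and 6 autosomal genes, among them Abat, which degrades the neurotransmitter GABA (log2 fold change -2.70, SE 0.43, adjusted p = 0.00471). At an unadjusted p under 0.05 there were 926 genes. The groups did not overlap for all 31, and for 33.2% of all tested genes, where chance gives 20%.

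Of the 19 primitive endoderm genes, the extra-embryonic lineage of the inner cell mass, 1 was called lower over all genes and 10 were lower adjusted over the list alone, with a median of -1.42 (adjusted p = 7.68e-10, but adjusted p = 0.169 with an estimated correlation). The laminin gene Lama1 of this list had a log2 fold change of -2.0 (SE 0.44, adjusted p = 0.0957). Between VIVO KO females and VIVO males the list had a median of -0.11 with none of 19 called (camera adjusted p = 0.393). Of the Xlr, Magea and Fthl17 families, none of 14 was called over all genes and 2 were higher adjusted over the list alone, with a median of 1.45 (adjusted p = 1.69e-08, but adjusted p = 0.131 with an estimated correlation). Of the 4 Rhox genes none was called over all genes and 3 were higher adjusted over the list alone, and Rhox5 had 34 ± 16 against 2.33 ± 3.3 RPKM (log2 fold change 3.93, SE 0.97, adjusted p = 0.103). No member was called over all genes in 5 further lists that passed the preset test. These were p53 targets (median 0.65, 4 of 17 higher adjusted over the list alone, adjusted p = 4.32e-06), the integrated stress response (median -0.57, 0 of 21 adjusted over the list alone, adjusted p = 6.3e-05), the unfolded protein and heat shock response (median 0.33, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0103), oxidative phosphorylation (median 0.36, 0 of 32, adjusted p = 4.54e-07) and cytosolic ribosomal proteins (median 0.44, 0 of 30, adjusted p = 2.84e-11). With an estimated correlation their adjusted p values were 0.131, 0.347, 0.169, 0.169 and 0.169.

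The number of calls in VIVO embryos was lower whichever embryo was left out, at 6, 16 and 8 without KO females 6, 7 and 8. Leaving out either of the 2 WT females leaves 1 embryo in that group. A call lost there does not show that a difference rests on single embryos. Hprt and Xist were called each time, Abat was lost without WT female 2 (adjusted p = 0.146), and Sox7 was lost without WT female 2 (0.214), KO female 6 (0.107) or KO female 7 (0.0582). Lefty2, Pgk1, Rlim and Arrdc4 were lost whichever of the 5 embryos was left out, with adjusted p from 0.0527 to 0.63.

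Measured within each embryo, the median of X-linked genes minus that of autosomal genes on log2(RPKM + 1) was 0.44 ± 0.22 in IVF KO females, -0.25 ± 0.03 in IVF WT females and -0.66 ± 0.07 in IVF males. It was 0.34 ± 0.21 in VIVO KO females, -0.48 ± 0.13 in VIVO WT females and -0.75 ± 0.11 in VIVO males. KO females exceeded WT females by 0.76 (0.69 within IVF and 0.83 within VIVO; exact permutation test within origin, two-sided, p = 0.005, the smallest that 200 permutations can give), and every KO female stood above every WT female.

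**Figure D2:**
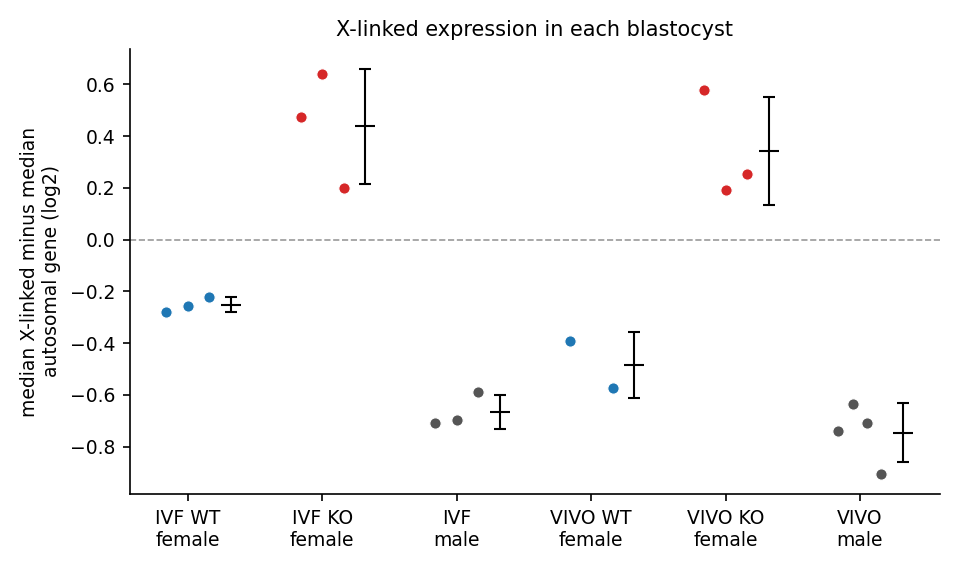
Median log2(RPKM + 1) of X-linked genes minus that of autosomal genes in each embryo, by group, with the group mean and SD in black and a dashed line at 0. KO females lie at 0.19 to 0.64, WT females at -0.57 to -0.22 and males at -0.91 to -0.59.

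**Figure D3:**
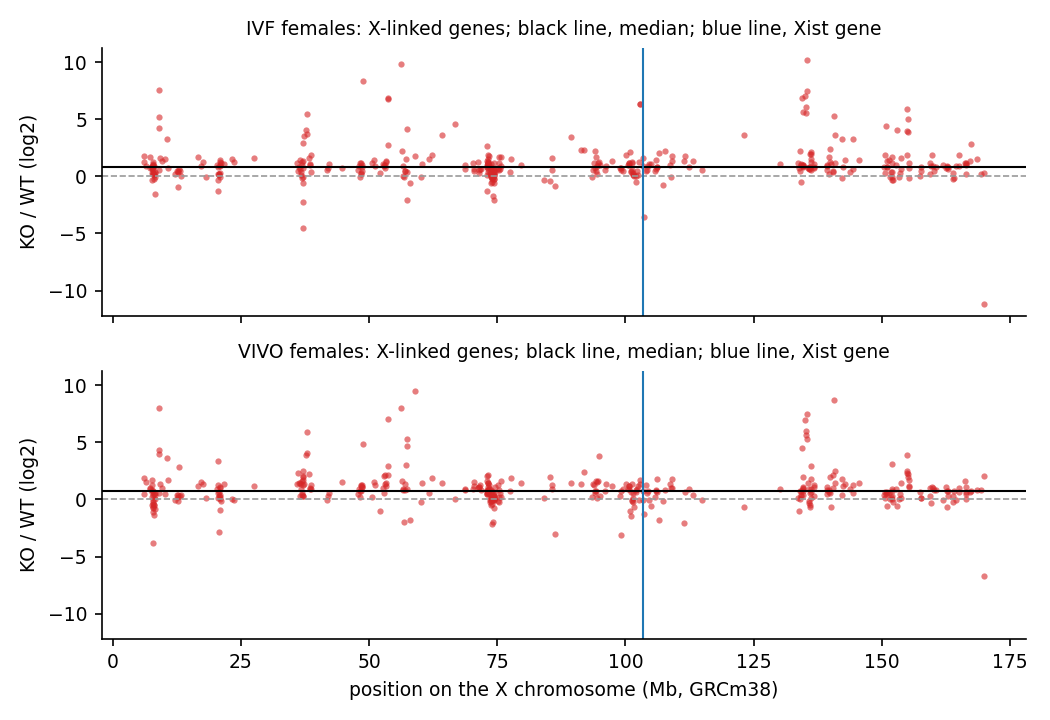
Log2 fold change of KO over WT females for X-linked genes along the X chromosome in megabases (GRCm38), for IVF and VIVO embryos. The black line is the median of X-linked genes, 0.86 in IVF and 0.78 in VIVO, and the blue line marks the Xist gene.

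Whether the effect of the deletion depends on origin was tested as a difference of differences. The X shift differed by 0.04 between origins (camera adjusted p = 0.483), and by -0.05 (without IVF KO female 4) to 0.14 (without VIVO KO female 6) with 1 embryo left out. Of single genes, only Rmrp (4, 43492785 to 43493059), the RNA component of an endoribonuclease, was called (log2 difference -2.99, SE 0.44, adjusted p = 0.0125). It stood at 836 ± 411 RPKM in IVF KO females (n = 3), 5908 ± 777 in IVF WT females (n = 3), 3783 ± 878 in VIVO KO females (n = 3) and 3705 ± 244 in VIVO WT females (n = 2). Lefty2 was not called, with 9.67 ± 13 and 1.34 ± 1.6 RPKM in IVF KO and WT females against 0 and 4.76 ± 0.77 in VIVO (adjusted p = 0.132). At an unadjusted p under 0.05 there were 872 genes. The planned limma test on log2(RPKM + 1) and its version with quantile normalization called 0 genes (Rmrp adjusted p = 0.052 and 0.0649). Rmrp was lost without VIVO WT female 2 (adjusted p = 0.357) or 3 (0.263), and 18 genes were called without IVF KO female 8. The preset test called 6 lists: Xlr, Magea and Fthl17 families (median 0.43), primitive endoderm (0.87), cholesterol synthesis (0.63), oxidative phosphorylation (-0.47), cytosolic ribosomal proteins (-0.59) and cell cycle (-0.30). None held with the stricter test (adjusted p from 0.704 to 0.793 with an estimated correlation).

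A comparison of WT females with males shows how far X-linked genes were balanced between the sexes. In IVF embryos the X shift of WT females (n = 3) over males (n = 3) was 0.33, or 1.26-fold (camera adjusted p = 2.35e-13, and adjusted p = 7.18e-05 with an estimated correlation). In VIVO embryos (n = 2 and n = 4) it was 0.19, or 1.14-fold (adjusted p = 1.04e-05, and adjusted p = 0.00363 with an estimated correlation). With no filter on expression the VIVO shift was 0. The X-to-autosome level was higher in WT females by 0.34 (0.41 within IVF and 0.26 within VIVO; exact permutation test within origin, two-sided, p = 0.00333, the smallest that 300 permutations can give).

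Between IVF WT females and males 7 genes were called, 2 higher and 5 lower in females, and 394 had an unadjusted p under 0.05. With each embryo's GC trend as an offset, 15 of 9821 genes were called, 9 of them X-linked besides Xist and higher in females, against 7 and 1 of the same genes without it. Xist rose to 353 ± 56.4 RPKM from 0.338 ± 0.073 (log2 fold change 10.08, SE 1.09, adjusted p = 0.00125), and Huwe1, an X-linked ubiquitin ligase, to 150 ± 16 from 96 ± 5.7 RPKM (log2 fold change 0.70, SE 0.14, adjusted p = 0.042). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at least 338, 170, 128 and 75.3-fold lower in females. The ion channel gene Trpa1 was at least 21.2-fold lower. Kdm6a, an X-linked histone demethylase that escapes inactivation, had 43 ± 2.6 against 23 ± 4.1 RPKM and was not called (log2 fold change 0.97, SE 0.19, adjusted p = 0.0568). Huwe1 was lost without IVF male 2 (adjusted p = 0.0646), 5 (0.241) or 6 (0.222) or WT female 2 (0.194) or 8 (0.232), and Trpa1 without WT female 2 (0.0637) or 8 (0.0619).

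Between VIVO WT females and males 17 genes were called, 12 higher and 5 lower in females, and 727 had an unadjusted p under 0.05. Besides Xist (log2 fold change 11.15, SE 1.01, adjusted p = 0.00021), the transcription factor gene Taf1 rose from 16.2 ± 1.8 to 37.4 ± 10 RPKM (log2 fold change 1.16, SE 0.21, adjusted p = 0.00896), and Kdm5c, an X-linked histone demethylase that escapes inactivation, from 17 ± 2.4 to 34.3 ± 1.4 RPKM (log2 fold change 0.97, SE 0.19, adjusted p = 0.0231). Sox7 was higher, at 6.77 ± 2.5 against 0.127 ± 0.15 RPKM (log2 fold change 5.44, SE 0.92, adjusted p = 0.00649), and Lefty2 and H19, an imprinted non-coding RNA, were at least 17.6 and 9.25-fold higher. Ddx3y, Eif2s3y, Uty and Kdm5d were at least 406, 173, 149 and 50.7-fold lower. Atp12a, a proton pump subunit, fell to 16.9 ± 1.6 from 72.6 ± 20 RPKM (log2 fold change -2.15, SE 0.36, adjusted p = 0.00493). The number of calls was 6 without VIVO WT female 2 and 10 without WT female 3. Taf1 (adjusted p = 0.717) and Sox7 (0.104) were lost without WT female 2, and Kdm5c, H19 and Atp12a without either of the WT females (0.0792 to 0.301). Kdm5c was also lost without male 1 (0.0535) or 5 (0.0808), H19 without male 1 (0.0535), 2 (0.0539) or 4 (0.0539), and Lefty2 without any 1 of the 6 embryos (0.0612 to 0.186).

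Of 9 tested genes that escape X inactivation, in IVF embryos none was called over all genes and 5 were higher adjusted over the list alone, with a median of 0.63 (adjusted p = 5.71e-10, and adjusted p = 0.00365 with an estimated correlation). In VIVO embryos 1 was called and 3 were higher adjusted over the list alone, with a median of 0.62 (adjusted p = 0.000273, but adjusted p = 0.0683 with an estimated correlation). All X-linked genes had medians of 0.31 in IVF and 0.17 in VIVO embryos, so the X shift can contribute to these results. No test set escape genes against other X-linked genes. The X-inactivation centre list, which holds Xist, passed both tests in both origins, with 1 of 5 members called each time and medians of 0.78 (adjusted p = 1.7e-09, and adjusted p = 0.000615 with an estimated correlation) and 0.32 (adjusted p = 0.000273, and adjusted p = 0.0254 with an estimated correlation). In VIVO embryos the DNA methylation list had no member called over all genes and 3 of 13 higher adjusted over the list alone, with a median of 0.42 (adjusted p = 0.00067, and adjusted p = 0.0472 with an estimated correlation). Primitive endoderm genes had medians of 0.71 in IVF, with none called, and 1.23 in VIVO embryos, with 1 of 19 called over all genes and 5 adjusted over the list alone (adjusted p = 1.01e-06 and 4.33e-09, but adjusted p = 0.29 and 0.147 with an estimated correlation). In the 2 origins 5 and 6 further lists passed the preset test and none of them held with an estimated correlation, where the adjusted p ran from 0.11 to 0.661.

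KO females were also set against males, which have 1 X chromosome and no Xist. In IVF embryos (n = 3 and n = 3) the X shift was 1.13, or 2.2-fold (camera adjusted p = 6.05e-66, and adjusted p = 4.22e-08 with an estimated correlation), and in VIVO embryos (n = 3 and n = 4) 0.97, or 1.96-fold (adjusted p = 8.37e-74, and adjusted p = 2.60e-08 with an estimated correlation). Eif2s3x, a translation initiation factor subunit that escapes inactivation, rose in both origins, in IVF from 175 ± 18 to 343 ± 84 RPKM (log2 fold change 1.0, SE 0.17, adjusted p = 0.00173) and in VIVO from 195 ± 22 to 356 ± 7.4 RPKM (log2 fold change 0.89, SE 0.16, adjusted p = 0.00281). Rhox5 rose in IVF from 6.98 ± 0.62 to 80.9 ± 32 RPKM (log2 fold change 3.53, SE 0.78, adjusted p = 0.0143) and in VIVO from 1.83 ± 1.4 to 34 ± 16 RPKM (log2 fold change 4.32, SE 0.76, adjusted p = 0.00281). Cox7b, an X-linked subunit of cytochrome c oxidase, rose in VIVO from 118 ± 22 to 268 ± 18 RPKM (log2 fold change 1.2, SE 0.19, adjusted p = 0.00111). The growth factor adaptor Gab1, a gene with non-canonical imprinting, and Klf5 fell in IVF KO females, with log2 fold changes of -1.17 (SE 0.20, adjusted p = 0.00205) and -0.99 (SE 0.17, adjusted p = 0.00168).

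Of 209 genes called in IVF embryos, 146 were higher in KO females, 109 of them X-linked, and 63 were lower, none of them X-linked. Of 124 called in VIVO embryos, 103 were higher, 92 of them X-linked, and 21 were lower, with Flna, an actin crosslinker, as the X-linked one (log2 fold change -3.07, SE 0.61, adjusted p = 0.026). Xist was higher in KO females than in males of IVF origin (log2 fold change 4.92, SE 0.90, adjusted p = 0.014) and was not called in VIVO (log2 fold change 2.48, SE 0.79, adjusted p = 0.254). Tsix was higher in VIVO KO females, at 16 ± 3.6 against 4.9 ± 2.5 RPKM (log2 fold change 1.74, SE 0.39, adjusted p = 0.0236). Y-linked genes were at least 239-fold (Ddx3y) and 120-fold (Eif2s3y) lower in IVF and at least 433-fold and 185-fold lower in VIVO. The metallothionein Mt2, which binds zinc, fell in IVF KO females (log2 fold change -1.10, SE 0.18, adjusted p = 0.000999) and in VIVO (log2 fold change -0.76, SE 0.17, adjusted p = 0.0193). The number of calls in IVF was 792 without KO female 8, and 138, 101 and 117 without males 2, 5 and 6. In VIVO it was 56 and 64 without KO females 6 and 8 and 75 and 77 without males 1 and 4. Xist and Rhox5 in IVF were lost without any of the 3 males (adjusted p from 0.0632 to 0.0811). In VIVO, Flna was lost without KO female 6 (0.135), 7 (0.0949) or 8 (0.0672) or male 1 (0.0556) or 4 (0.0607), and Tsix without KO female 6 (0.155) or 8 (0.0672) or male 4 (0.079) or 5 (0.0852). Mt2 in VIVO was lost without KO female 6 (0.104) or 8 (0.174) or male 1 (0.073). Eif2s3x in both origins, Cox7b and Rhox5 in VIVO and Klf5, Gab1 and Mt2 in IVF were called with any 1 embryo left out.

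Escape genes had 3 of 9 members called in IVF and 4 in VIVO, 6 in each adjusted over the list alone, with a median of 0.89 in both (adjusted p = 8.36e-08 and 4.45e-10, and adjusted p = 0.0131 and 0.00706 with an estimated correlation). This was below the medians of all X-linked genes, 1.12 in IVF and 0.94 in VIVO. All members of this list, of the X-inactivation centre and of the Xlr, Magea and Fthl17 families are X-linked. The X shift alone can thus make these lists pass. The X-inactivation centre list had 3 and 2 of 5 called and passed both tests in both origins (medians 1.82 and 1.09, adjusted p = 0.00321 and 0.0106 with an estimated correlation). The Xlr, Magea and Fthl17 families had 5 of 14 called in IVF, 12 adjusted over the list alone (median 1.86, adjusted p = 2.55e-14, and adjusted p = 0.0131 with an estimated correlation), and in VIVO none. There 1 was higher adjusted over the list alone (median 0.77, adjusted p = 8.7e-05, but adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis was higher in IVF KO females than in males, with 3 of 21 members called, among them Cyp51, and 8 adjusted over the list alone (median 0.85, adjusted p = 9.61e-08, but adjusted p = 0.0638 with an estimated correlation). Cyp51, the lanosterol demethylase, had 19.9 ± 2.74 against 6.96 ± 1.41 RPKM (log2 fold change 1.54, SE 0.30, adjusted p = 0.00479). Targets of p53 had 1 of 17 members called in VIVO, Pmaip1, a pro-apoptotic gene, and 2 adjusted over the list alone (median 0.95, adjusted p = 9.55e-07, and adjusted p = 0.0327 with an estimated correlation). Pmaip1 itself was lost without VIVO KO female 6 (0.278) or 8 (0.0978) or male 1 (0.073), 2 (0.0976) or 4 (0.0974). The other lists that passed the preset test, 3 in IVF and 5 in VIVO, did not hold with an estimated correlation, where the adjusted p ran from 0.188 to 0.83.

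The second question was how embryos fertilised in vitro differ from those flushed from the mother. Over the 3 classes (9 IVF and 9 VIVO embryos), 1592 genes were called in the mean of the origin differences, 776 higher and 816 lower in IVF, with 2965 genes at an unadjusted p under 0.05. The maternal and pluripotency gene Dppa3 (6, 122626424 to 122630271) fell in IVF embryos (log2 fold change -2.92, SE 0.22, adjusted p = 1.32e-07). Its group means were 84.7 ± 44.1 against 554 ± 292 RPKM in WT females, 153 ± 49.8 against 1107 ± 210 in KO females and 92 ± 20.3 against 825 ± 202 in males. Sox7 rose (log2 fold change 4.54, SE 0.57, adjusted p = 1.03e-05), as did the trophectoderm transcription factor Elf5 (1.57, SE 0.20, adjusted p = 7.6e-06). The rise of Sox7 was larger in KO females and in males, given below, than in this mean, and so smaller in WT females. H19 was called higher in IVF (adjusted p = 4.77e-06), with no count in VIVO males. Lefty2 was called higher in the mean (adjusted p = 0.00032), with no count in VIVO KO females or males, but stood at 1.34 ± 1.6 in IVF against 4.76 ± 0.77 RPKM in VIVO WT females. Mgarp, a mitochondrial protein gene, fell (log2 fold change -5.04, SE 0.55, adjusted p = 1.16e-06), and Gulo, with no count in IVF WT females, was called lower (adjusted p = 2.65e-06). All of these were called with any 1 of the 18 embryos left out.

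Of 19 primitive endoderm genes 12 were called higher and 2 lower in IVF, the same numbers adjusted over the list alone, with a median of 1.45. Lama1 and Lamc1, laminin subunits, rose by 1.96 (SE 0.25, adjusted p = 6.25e-05) and 1.12 (SE 0.18, adjusted p = 0.000259) on the log2 scale. The list passed the preset test (adjusted p = 7.04e-07, but adjusted p = 0.321 with an estimated correlation). Of 27 epiblast and pluripotency genes 7 were called lower and none higher, against 7 lower and 1 higher adjusted over the list alone (median -0.23, adjusted p = 0.00301, but adjusted p = 0.321 with an estimated correlation). Nanog, a core pluripotency factor, fell by 1.29 (SE 0.26, adjusted p = 0.00167) and Dppa2 by 1.12 (SE 0.17, adjusted p = 6.25e-05) on the log2 scale. Of 29 trophectoderm genes 10 were called higher and 4 lower, 11 and 4 adjusted over the list alone (median 0.11, adjusted p = 0.0363, but adjusted p = 0.456 with an estimated correlation). The keratin Krt19 rose by 4.40 (SE 0.77, adjusted p = 0.000311) and the growth factor receptor Fgfr2 by 0.70 (SE 0.10, adjusted p = 2.91e-05). MAPK feedback genes, induced by growth factor signalling, had 5 of 12 called higher and 6 adjusted over the list alone (median 1.22, adjusted p = 0.00456, but adjusted p = 0.321 with an estimated correlation). Among them were Dusp9 at 2.25 (SE 0.40, adjusted p = 0.000339) and Dusp6 at 1.2 (SE 0.28, adjusted p = 0.00567).

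Of 21 genes of the integrated stress response 15 were called higher in IVF and none lower, against 15 and 2 adjusted over the list alone (median 1.16, adjusted p = 3.45e-13, but adjusted p = 0.11 with an estimated correlation). Among them, Sesn2, a sensor of amino acid shortage, rose by 1.32 (SE 0.17, adjusted p = 1.04e-05), the amino acid transporter subunit Slc3a2 by 1.15 (SE 0.15, adjusted p = 1.39e-05) and Shmt2, of mitochondrial one-carbon metabolism, by 1.51 (SE 0.24, adjusted p = 9.63e-05) on the log2 scale. Of 17 p53 targets 9 were called higher and 1 lower, 12 and 1 adjusted over the list alone (median 0.88, adjusted p = 3.71e-06, but adjusted p = 0.104 with an estimated correlation). Phlda3, a repressor of AKT, rose by 2.41 (SE 0.41, adjusted p = 0.00026) and the cell cycle inhibitor Cdkn1a by 1.79 (SE 0.39, adjusted p = 0.00227). Sesn2 is on that list as well. Of 21 genes of cholesterol synthesis none was called higher and 10 lower, 11 lower adjusted over the list alone (median -0.69, adjusted p = 3.13e-07, but adjusted p = 0.11 with an estimated correlation). Its members Fdft1, squalene synthase, and Ebp, a sterol isomerase, fell by 1.33 (SE 0.19, adjusted p = 3.8e-05) and 1.31 (SE 0.21, adjusted p = 9.83e-05). Of 25 cell cycle genes none was called higher and 11 lower, 13 adjusted over the list alone (median -0.56, adjusted p = 1.55e-09, but adjusted p = 0.105 with an estimated correlation). The mitotic kinase gene Aurka changed by -1.22 (SE 0.14, adjusted p = 2.25e-06) and cyclin B2 (Ccnb2) by -1.07 (SE 0.14, adjusted p = 1.43e-05). Of 30 cytosolic ribosomal proteins 7 were called higher and none lower, 8 adjusted over the list alone (median 0.12, adjusted p = 0.0338, but adjusted p = 0.583 with an estimated correlation).

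The X shift between origins was 0.08 in this mean and was not called (camera adjusted p = 0.112), and the X-to-autosome level was higher in IVF embryos by 0.14 (0.23 in WT females, 0.10 in KO females and 0.08 in males; exact permutation test within classes, two-sided, p = 0.0609). The X shift was called without IVF KO female 8 (0.12, adjusted p = 0.0304). The level passed the threshold without IVF KO female 8 (0.18, p = 0.021), VIVO KO female 6 (0.18, p = 0.018) or VIVO male 2 (0.15, p = 0.042), all by the same exact permutation test. With no filter on expression the level passed as well. The count of called genes was 1027 without VIVO WT female 3.

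**Figure D4:**
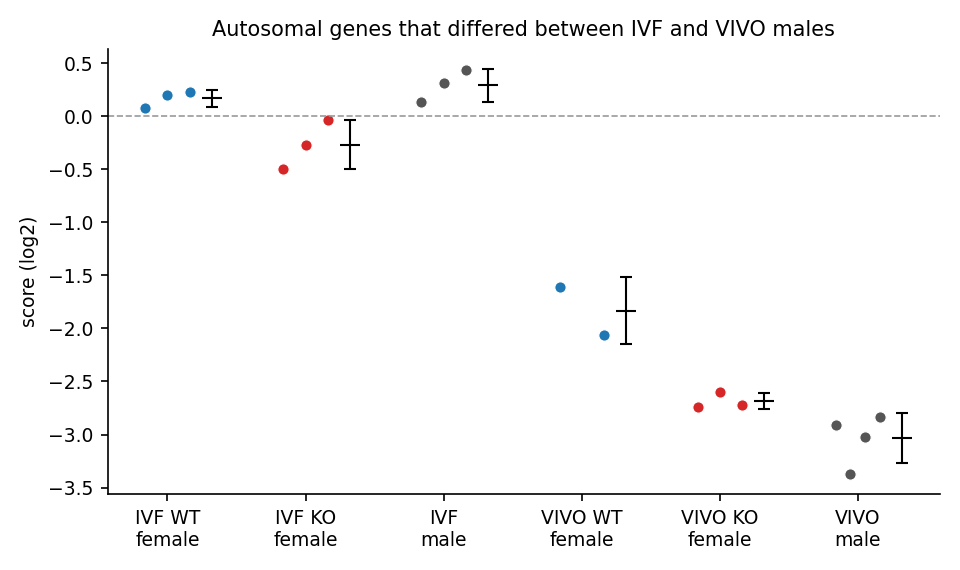
Score of each embryo over the autosomal genes called between IVF and VIVO males, as the mean of the 167 higher genes minus that of the 259 lower genes on the log2 scale, by group, with the mean and SD in black. VIVO males lie at -3.03 ± 0.24, VIVO KO females at -2.69 ± 0.07, VIVO WT females at -1.83 ± 0.32 and the IVF groups between -0.27 and 0.29; the males are the embryos from which the genes were chosen.

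Between IVF (n = 3) and VIVO WT females (n = 2) 87 genes were called, 35 higher and 52 lower in IVF, with 1160 at an unadjusted p under 0.05. The groups did not overlap for all 87, and for 35.5% of all tested genes, where chance gives 20%. Psat1, of serine synthesis, rose from 51.8 ± 13.4 to 180.2 ± 17.6 RPKM (log2 fold change 1.85, SE 0.34, adjusted p = 0.00541), and Slc6a14, an X-linked amino acid transporter, from 34.3 ± 3.76 to 109 ± 20.7 RPKM (log2 fold change 1.73, SE 0.27, adjusted p = 0.00196). The cardiac transcription factor Tbx20 fell from 26.3 ± 3.10 to 2.64 ± 1.40 RPKM (log2 fold change -3.25, SE 0.54, adjusted p = 0.00623), and Gulo and Trpa1 were at least 22.1 and 17.5-fold lower. Xist had 353 ± 56.4 against 834 ± 40.6 RPKM, with no overlap, but was not called (log2 fold change -1.19, SE 0.80, adjusted p = 0.673). The spread was fitted over all 6 groups, and Xist ran from 1.47 to 19.1 RPKM in IVF KO females. This p thus does not measure the spread of WT females alone. Of the 21 genes of the integrated stress response 1 was called over all genes and 14 were higher adjusted over the list alone (median 1.25, adjusted p = 2.51e-13, but adjusted p = 0.129 with an estimated correlation). The other 7 lists that passed the preset test were lost as well (adjusted p from 0.129 to 0.499 with an estimated correlation). They were p53 targets (median 0.84, 2 higher), cholesterol synthesis (-0.71, 1 lower), cytosolic ribosomal proteins (0.43, none), cell cycle (-0.46, none), epiblast and pluripotency (-0.44, 1 lower), primitive endoderm (0.88, none) and DNA methylation (-0.28, 1 lower). The number of calls was 6 without VIVO WT female 3, 43 without VIVO WT female 2, and 39 and 56 without IVF WT females 4 and 8. Without VIVO WT female 3, Psat1 (adjusted p = 0.202), Slc6a14 (0.0643) and Tbx20 (0.0824) were lost.

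Between IVF and VIVO KO females (n = 3 and n = 3) 547 genes were called, 257 higher and 290 lower in IVF, with 2202 at an unadjusted p under 0.05. The groups did not overlap for 524 of the 547, and for 21.6% of all tested genes, where chance gives 10%. H19 rose from 0.0376 ± 0.065 to 11.9 ± 7.6 RPKM (log2 fold change 7.82, SE 1.2, adjusted p = 0.000749). Sox7 rose from 0.0972 ± 0.17 to 10.2 ± 8.8 RPKM (6.52, SE 1.03, adjusted p = 0.000842) and the heme oxygenase Hmox1 from 3.46 ± 0.65 to 25.2 ± 9.7 RPKM (2.78, SE 0.40, adjusted p = 0.000253). Spic, a transcription factor of the Ets family, fell from 12.5 ± 2.2 to 0.17 ± 0.24 RPKM (log2 fold change -6.40, SE 1.09, adjusted p = 0.00137) and Klf5 had a log2 fold change of -0.83 (SE 0.17, adjusted p = 0.00512). Primitive endoderm had 6 of 19 members called higher and 13 higher and 1 lower adjusted over the list alone (median 1.76, adjusted p = 1.33e-07). The integrated stress response had 7 of 21 called higher and 13 higher and 1 lower adjusted over the list alone (median 1.15, adjusted p = 1.04e-07). Cell cycle had 6 of 25 called lower and 8 adjusted over the list alone (median -0.63, adjusted p = 6.82e-08). None of the 3 held with the stricter test (adjusted p = 0.31 with an estimated correlation for each). In cholesterol synthesis Cyp51 rose by 1.58 (SE 0.30, adjusted p = 0.00313) while Ebp fell by 1.70 (SE 0.36, adjusted p = 0.00675). A further 6 lists passed the preset test and were lost with an estimated correlation (adjusted p from 0.315 to 0.548). They were the Xlr, Magea and Fthl17 families (median 0.75), p53 targets (0.71), epiblast and pluripotency (-0.20), unfolded protein and heat shock response (-0.43), oxidative phosphorylation (-0.31) and cytosolic ribosomal proteins (-0.18).

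The X shift in this comparison was 0.16 (camera adjusted p = 0.0357, but adjusted p = 0.110 with an estimated correlation). It was no longer called without IVF KO female 3 (0.18, adjusted p = 0.17) or 4 (0.11, adjusted p = 0.24) or VIVO KO female 7 (0.14, adjusted p = 0.095) or 8 (0.17, adjusted p = 0.086). The number of called genes was 865 without IVF KO female 8 and 289, 337 and 231 without VIVO KO females 6, 7 and 8.

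Between IVF and VIVO males (n = 3 and n = 4) 445 genes were called, 178 higher and 267 lower in IVF, with 1885 at an unadjusted p under 0.05. The groups did not overlap for 410, and for 19% of all tested genes, where chance gives 5.71%. Igf2 rose from 7.03 ± 1.9 to 21.8 ± 4 RPKM (log2 fold change 1.57, SE 0.25, adjusted p = 0.000635). Sesn2 rose from 11.9 ± 2.5 to 37.6 ± 6.3 RPKM (1.60, SE 0.27, adjusted p = 0.00108) and Sox7 from 0.127 ± 0.15 to 9.94 ± 4.8 RPKM (5.98, SE 0.89, adjusted p = 0.00044), while Lefty2 and H19 were at least 32.6 and 18.6-fold higher. Fdft1 fell from 25.1 ± 10 to 7.67 ± 1.4 RPKM (log2 fold change -1.77, SE 0.32, adjusted p = 0.00216) and the isopentenyl diphosphate isomerase Idi1 by 1.65 (SE 0.32, adjusted p = 0.00312). Cholesterol synthesis had 6 of 21 members called lower and 13 adjusted over the list alone (median -1.03, adjusted p = 7.18e-11, but adjusted p = 0.09 with an estimated correlation). Cell cycle had 6 of 25 called lower and 12 adjusted over the list alone (median -0.64, adjusted p = 7.33e-08, but adjusted p = 0.115 with an estimated correlation). Primitive endoderm had 4 called higher and 1 lower, 13 and 2 adjusted over the list alone (median 1.70, adjusted p = 2.38e-05, but adjusted p = 0.361 with an estimated correlation). The integrated stress response had 4 called higher and 12 adjusted over the list alone (median 1.0, adjusted p = 7.33e-08, but adjusted p = 0.268 with an estimated correlation). Targets of p53 (median 0.81), MAPK feedback (1.39) and cytosolic ribosomal proteins (0.26) passed the preset test and were lost as well (adjusted p = 0.101, 0.268 and 0.662 with an estimated correlation). The number of calls was 263 and 227 without IVF males 5 and 6 and 270 without VIVO male 2. The X shift between males was -0.02 (camera adjusted p = 0.702), and between WT females 0.07 (adjusted p = 0.147). With 1 embryo left out these ran from -0.05 to 0.00 and from 0.05 to 0.11.

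Whether origin acted differently on WT females and males was tested as a difference of differences. By edgeR's quasi-likelihood test 0 genes were called, with 418 at an unadjusted p under 0.05, and limma on log2(RPKM + 1) called 0, limma with array weights 1 and DESeq2 5. The smallest p values were those of Atp12a, at 37.3 ± 12 and 16.9 ± 1.6 RPKM in IVF and VIVO WT females against 33.6 ± 4.2 and 72.6 ± 20 in males (adjusted p = 0.139), and Lefty2 (adjusted p = 0.139). The X shift differed by 0.11 (camera adjusted p = 0.241), and by 0.06 (without VIVO male 1) to 0.16 (without VIVO WT female 3) with 1 embryo left out. Oxidative phosphorylation (0.31), cytosolic ribosomal proteins (0.19) and DNA methylation (-0.43) passed the preset list test and none held with the stricter one (adjusted p = 0.586, 0.586 and 0.35 with an estimated correlation).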

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

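The tests of whether 2 embryos set the shift, of a whole autosome, of carried-over cells and of maturity were chosen with the results known. The kinds of test for GC content, depth and other splits of the embryos were chosen before. In the second pattern, however, GC content and depth were tested on 2 embryos picked after the data were seen. They were picked for holding the fewest detected genes, and the depth test there counts detected genes as well.

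The first pattern is the X shift between IVF and VIVO KO females, 0.16 on the log2 scale. Against autosomal genes matched on GC content and length it was 0.167, and with each embryo's GC trend as an offset 0.147, against 0.16 for the same genes without either. The interval of the matched value, 0.044 to 0.235, comes from 2000 resamples of X-linked genes and does not cover the spread between embryos. It reaches under the 0.08 set for GC content bias as the cause. Neither correction removed the shift, but with so wide an interval GC content bias cannot be told apart from a biological effect. Without IVF KO females 3 and 4 the shift was -0.03193, but this leaves 1 IVF KO female, with the spread taken from the other groups. It was 0.18 without embryo 3 and 0.11 without embryo 4, so whether 2 embryos set the shift stays open. Of the 10 splits of these 6 embryos 2 had an X shift as large, the real 0.1641 and another at 0.2552. The splits are too few for a share under 0.05.

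The second pattern is that IVF KO females 3 and 4 stand apart from the other 16 embryos. Their deviations from the mean of the groups had rank correlations with GC content of -0.2544 and -0.296. The other 16 embryos lay between -0.173 and 0.351, the highest being IVF KO female 8 of the same group. These values cannot tell GC content bias from other causes. GC content as the whole cause is ruled out, since 0.4974 of median absolute deviation remained with the trend removed, against at most 0.348 in IVF WT females, 0.434 in IVF KO female 8 and 0.410 in VIVO male 4, the highest of the others. Fewer reads are ruled out too: at equal totals the higher of the 2 had 11126 genes with a count and the other embryos 11184 to 12417. The largest median deviation of an autosome was -0.2105, short of the 0.292 set for gain or loss of a whole autosome; no biological explanation beyond this was tested.

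The third pattern is the 1592 genes that differ between IVF and VIVO embryos. With every embryo thinned to the smallest total 1619 genes were called, 1499 of them shared, so sequencing depth is ruled out. With each embryo's GC trend as an offset 1710 were called, against 1519 of the same 9821 genes without it. Of 48 listed markers of reproductive tract, blood and sperm with a value 6 reached 1 RPKM in IVF and 3 in VIVO embryos. This argues against a carry-over of all these cells together as the main cause. The markers were pooled, so cells of 1 type alone could not make up the majority set for this cause. Carry-over of 1 cell type thus stays open. Maturity of the blastocysts cannot be told apart from an effect of the deletion: over the 426 autosomal genes called between males, VIVO WT females scored 0.8514 above VIVO KO females, and so lay between VIVO males and the IVF groups. WT females lay above KO females in IVF as well, at 0.168 against -0.270 with no overlap.

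Other splits of the embryos were compared with the real grouping. For KO against WT females of IVF origin, 1 of 10 splits called as many genes as the real 107 (highest other 0) and 1 of 10 had as large an X shift (0.8464, highest other 0.4289). For IVF against VIVO KO females 1 of 10 called as many as 547 (highest other 1). For WT females against males of IVF origin 1 of 10 called as many as 7 (highest other 0) and 1 of 10 had as large an X shift (0.3282, highest other 0.1482). For KO females against males of IVF origin 1 of 10 called as many as 209 (highest other 17) and 1 of 10 had as large an X shift (1.135, highest other 0.5861). In each of these, 10 splits are too few for a share under 0.05.

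With more splits, the real grouping gave the largest result for the calls of KO females against males of VIVO origin (1 of 35 splits, 124 against 7). It did so for their X shift too (1 of 35, 0.9738 against 0.812). The calls between IVF and VIVO males were also the largest (1 of 35, 445 against 60), but not their X shift (15 of 35, 0.02291 in size against 0.05893). So were the calls in the mean of the origin comparisons (1 of 100, 1592 against 33), but not the X shift there (10 of 100, 0.08168 against 0.1048). A share of 1 of 35 is under 0.05 but is the smallest that these splits allow. The shares were not adjusted over the tests, and embryos of 1 litter may not be exchangeable. Chance is thus less likely where the real grouping was the largest, but not excluded.

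Bex1, an X-linked gene of neural signalling, stood at 4.24 RPKM in VIVO male 2, far from the 0 to 0.425 RPKM of the other VIVO males. It was the single such value in 36 measures tested, where chance alone gives 1.8. All were measures of VIVO males, the only group large enough for this test, so the other groups were not screened.

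In the test of whether the effect of the deletion differs between origins, edgeR called Rmrp (-2.986). The planned limma test on log2(RPKM + 1) called 0 genes (Rmrp adjusted p = 0.052), and Rmrp was lost with quantile normalization (0.0649), so this call depends on the test. It was also lost without VIVO WT female 2 or 3, but that leaves 1 embryo in the group. The loss therefore does not show that the difference rests on single embryos. The preset list test called the Xlr, Magea and Fthl17 families (0.4254), primitive endoderm (0.8745), cholesterol synthesis (0.6299), oxidative phosphorylation (-0.4703), cytosolic ribosomal proteins (-0.5925) and cell cycle (-0.2956). The effect of origin differed between WT females and males for oxidative phosphorylation (0.3058), cytosolic ribosomal proteins (0.1934) and DNA methylation (-0.4329). None of these lists held with an estimated correlation.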

How the results depend on the processing

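Of 465 named gene results, DESeq2 kept 440 on the same side of the threshold, edgeR with DESeq2 size factors 462, no filter 432, limma on log2(RPKM + 0.1) 392, limma on log2(RPKM + 1) 379, quantile normalization 377, the deposited log2 RPKM 364, array weights 352 and the replicate block 259. Only the groups compared kept 266 of 362, leaving out 1 embryo 3489 of 4266, and leaving out IVF KO females 3 and 4 together 169 of 259. One named gene reversed: Rlim between IVF and VIVO KO females was -0.76 without embryos 3 and 4. Leaving out both leaves 1 IVF KO female, so the spread there comes from the other groups and the values given without them decide nothing. Quantile normalization and array weights were run within limma on log2(RPKM + 1), so here they change the test as well. The X shifts between KO and WT females and between KO females and males, the Xist level and the X-to-autosome levels of KO against WT females and of WT females against males kept direction and call under every alternative run for them. For the levels these were leaving out 1 embryo, the pseudocount 0.1, quantile normalization and, for the X-to-autosome level, no filter.

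KO against WT females of IVF origin (107 calls) gave 314 with no filter, 215 with limma and quantile normalization, 30 with limma and array weights, 28 with the replicate block, 30 with only the groups compared, 174 with limma on log2(RPKM + 1), 295 with DESeq2, 179 with the deposited log2 RPKM and 17 without IVF KO females 3 and 4. Leaving out 1 embryo gave 27 (without IVF WT female 8) to 641 (without IVF KO female 8). That of VIVO origin (31 calls) gave 11 with limma on log2(RPKM + 0.1), 182 with no filter, 15 with limma and quantile normalization, 153 with limma and array weights, 182 with only the groups compared, 12 with limma on log2(RPKM + 1), 118 with DESeq2 and 19 with the deposited log2 RPKM. Leaving out 1 embryo gave 2 (without VIVO WT female 2) to 16 (without VIVO KO female 7). The difference of the 2 (1 call) gave 3 with limma on log2(RPKM + 0.1), 101 with no filter, 0 with limma and quantile normalization, 2 with limma and array weights, 3 with the replicate block, 3 with only the groups compared, 0 with limma on log2(RPKM + 1), 38 with DESeq2, 7 without IVF KO females 3 and 4, and 0 (without VIVO WT female 2) to 18 (without IVF KO female 8) leaving out 1 embryo.

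IVF against VIVO WT females (87 calls) gave 347 with no filter, 494 with limma and array weights, 32 with the replicate block, 403 with only the groups compared, 255 with DESeq2, and 6 (without VIVO WT female 3) to 70 (without IVF WT female 2) leaving out 1 embryo. KO females (547 calls) gave 842 with no filter, 122 with limma and array weights, 194 with the replicate block, 177 with only the groups compared, 954 with DESeq2, and 231 (without VIVO KO female 8) to 865 (without IVF KO female 8). Males (445 calls) gave 818 with no filter, 799 with limma and array weights, 171 with the replicate block, 784 with DESeq2, and 227 (without IVF male 6) to 389 (without VIVO male 5). The mean of the 3 (1592 calls) gave 1027 (without VIVO WT female 3) to 1791 (without IVF KO female 3). The difference between WT females and males (0 calls) gave 56 with no filter, 1 with limma and array weights, 2 with only the groups compared, 5 with DESeq2, and 0 to 1 (without IVF male 5) leaving out 1 embryo.

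WT females against males of IVF origin (7 calls) gave 72 with no filter, 13 with limma and array weights and 27 with DESeq2. Those of VIVO origin (17 calls) gave 11 with limma on log2(RPKM + 0.1), 150 with no filter, 9 with limma and quantile normalization, 36 with limma and array weights, 29 with only the groups compared, 8 with limma on log2(RPKM + 1), 63 with DESeq2, 10 with the deposited log2 RPKM, and 6 (without VIVO WT female 2) to 18 (without VIVO male 2). KO females against males of IVF origin (209 calls) gave 388 with no filter, 93 with limma and array weights, 24 with the replicate block, 24 with only the groups compared, 441 with DESeq2, 81 without IVF KO females 3 and 4, and 101 (without IVF male 5) to 792 (without IVF KO female 8). Those of VIVO origin (124 calls) gave 292 with no filter, 81 with limma and quantile normalization, 193 with limma and array weights, 23 with the replicate block, 209 with DESeq2, and 56 (without VIVO KO female 6) to 101 (without VIVO male 2).

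The X shift between IVF and VIVO KO females (0.16) was 0.142 with the replicate block, 0.164 with an estimated correlation, 0.163 with DESeq2 and -0.032 without IVF KO females 3 and 4, none of them called, and 0.113 to 0.251 leaving out 1 embryo. That of WT females was 0.195 with the replicate block and 0.0455 to 0.109 leaving out 1 embryo, that of males -0.0532 to 0.00187, that of the mean 0.0605 to 0.12 leaving out 1 embryo, and that of the difference between WT females and males 0.130 with the deposited log2 RPKM and 0.0643 to 0.165 leaving out 1 embryo. The difference of the KO effect between origins ran from -0.053 to 0.145. With no filter the X shift of VIVO WT females over males was 0. The X-to-autosome level of IVF over VIVO embryos was 0.147 with no filter, where it passed its threshold, and 0.103 to 0.176 leaving out 1 embryo. With an estimated correlation 11 of 88 list calls remained.

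With no filter 16383 genes entered and the prior degrees of freedom rose from 12.0 to infinity, and of the 314 calls for KO against WT females of IVF origin 306 are genes that also pass the filter. Whether the numbers in the labels pair embryos is not stated. Deviations of the 15 same-number pairs correlated at a median of 0.0066, against -0.0033 in the 119 other pairs. This gives no sign of pairing but cannot exclude it with so few embryos per group, so the replicate block is kept as an alternative. The cause of the other changes was not tested. Depth limits genes under 3 counts per library.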

Other observations

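The test of distance from Xist was chosen before and the test of less silencing in IVF WT females only after the result was seen.

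The lists below did not pass camera, which sets a list against the other genes, or had too few tested members for it, between IVF and VIVO embryos in the mean of the origin differences (9 and 9 embryos), where 1592 of all 10425 genes were called, so single calls in a list do not set it apart. The mixed test of fry, which makes no such comparison, passed for all lists below that were tested (adjusted p up to 0.000321). It did not pass for the X-inactivation centre (adjusted p = 0.972). That list did not pass camera either (adjusted p = 0.598), with 1 of 5 members called higher. The directional test of fry passed for escape genes, canonical imprinted genes, the unfolded protein and heat shock response, DNA methylation and apoptosis (adjusted p from 0.0019 to 0.0321). Of 21 oxidative stress genes 3 were called higher and 7 lower, 4 and 8 adjusted over the list alone (median -0.10, adjusted p = 0.24). Hmox1 rose by 1.97 (SE 0.23, adjusted p = 2.25e-06) and Me1, malic enzyme, fell by 1.11 (SE 0.15, adjusted p = 1.79e-05). Of 17 genes of the unfolded protein and heat shock response 2 were higher and 4 lower, 2 and 5 adjusted over the list alone, with the chaperones Hspb1 at 1.74 (SE 0.30, adjusted p = 0.00026) and Hspa8 at -0.65 (SE 0.08, adjusted p = 5.53e-06). Of 18 glycolysis genes 3 were higher and none lower, 4 adjusted over the list alone, with Pgk1 at 0.97 (SE 0.18, adjusted p = 0.000529). Of 17 apoptosis genes 2 were lower, 1 higher and 2 lower adjusted over the list alone, and of 32 genes of oxidative phosphorylation 2 were lower, with Atp5j at -0.75 (SE 0.15, adjusted p = 0.00133).

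Of 26 Polycomb genes 1 was called higher and 2 lower, with Suz12, a core subunit, at -0.50 (SE 0.13, adjusted p = 0.011), and of 13 DNA methylation genes 2 were higher and 3 lower, with the dioxygenase Tet2 at -0.88 (SE 0.12, adjusted p = 1.75e-05). Of 25 canonical imprinted genes 4 were higher, among them Igf2 at 0.82 (SE 0.16, adjusted p = 0.000942), and of 16 non-canonical ones 2 were higher and 1 lower, 5 and 1 adjusted over the list alone, with Epas1, a hypoxia factor, at -1.17 (SE 0.16, adjusted p = 1.79e-05). Of 9 escape genes 3 were higher, among them Ddx3x at 0.54 (SE 0.11, adjusted p = 0.0021), and of the 4 Rhox genes 3, among them Rhox6 (adjusted p = 0.0086). Of 4 oocyte genes 1 was lower, Khdc3, a maternal gene, at -0.63 (SE 0.12, adjusted p = 0.000659), with 2 adjusted over the list alone, and of 10 genes of the 2-cell stage 1 was higher and 3 lower, 3 and 3 adjusted over the list alone (median 0.62, mean 0.38, test down, adjusted p = 0.85). Of the cumulus list Nr5a2 was lower at -0.52 (SE 0.11, adjusted p = 0.00215), of the oviduct list Msx1 higher (adjusted p = 0.000229) and of the blood list S100a9 higher (adjusted p = 0.0221), and no sperm or mitochondrially encoded gene entered the test. S100a9 was lost without IVF KO female 3 (adjusted p = 1) or IVF male 2 (adjusted p = 1), or VIVO WT female 2 (0.078) or 3 (0.0802). The Xlr, Magea and Fthl17 families had 2 higher and 1 lower, 2 and 3 adjusted over the list alone, with a median of 0.36 but a mean of -0.25 (adjusted p = 0.528).

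Whether genes nearer Xist rise more without Xist was tested on the KO to WT female fold along the X chromosome. The rank correlation of distance and fold was 0.01899 (permutation test by circular shift, p = 0.293), and 64 genes within 10 Mb of Xist had a median of 0.73 against 0.84 in the 342 others. No such gradient was found.

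Xist was lower in IVF than in VIVO WT females, at 353 ± 56.4 against 834 ± 40.6 RPKM. It was not called, in a test whose spread also takes in the KO females. If the lower Xist meant less silencing, X-linked genes of WT females relative to males would be higher in IVF. The difference was 0.1126, or 0.0643 to 0.165 leaving out 1 embryo, which cannot tell.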
